A study of Homo sapiens with 8 samples.

How the data were processed

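RNA of the cytoplasm was sequenced from 6 MCF7 libraries (2 each of siHNRNPC, siNC and siLAMN) and 2 T47D libraries (1 each of siHNRNPC and siNC). Per the labels' protocols, siRNAs were reverse transfected at 10 nM with Lipofectamine RNAiMAX, the medium was changed after 6 h and cells were harvested at 48 h. Per the same protocols, nuclei and cytosol were separated with a Biovision kit, cytosolic RNA was purified with Trizol and treated with Turbo DNase, ribosomal RNA was removed with Ribo-Zero, and about 100 ng of depleted RNA entered the TruSeq RNA kit. What siLAMN targets is not stated beyond its label.

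The values used were expected counts per gene, deposited by the authors as 1 table per library. The submitters' processing notes name CASAVA 1.8, cutadapt 1.11, RSEM 1.2.15, Bowtie2 2.1.0 and the genome hg38. The annotation release, the strand setting and any filters are not given in the sources used here. Every value was a whole number, so the deposited expected counts were taken as rounded before deposit. Each table held 60498 genes, of which 56913 (94.1%) were named from GENCODE 29 and 3585 were left without a name. Of 50 Y copies of pseudoautosomal genes 24 held a read, and 21 of these were within 1 read of the X copy, so these genes may be counted on both.

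The MCF7 libraries held between 6043157 and 9257355 reads in genes, with 17838 to 18860 genes detected. The T47D libraries held 17511377 and 14764395, with 27842 and 26705 genes detected. A floor of 3 reads equals 0.324 to 0.496 CPM in MCF7 and 0.171 and 0.203 CPM in T47D, on total reads before TMM scaling. Protein-coding genes took 69.1% to 80.6% of MCF7 reads and 63.0% and 65.1% of T47D reads, and mitochondrial ribosomal RNA took 17.9% and 19.4% of T47D reads. TMM factors lay between 0.918 and 1.08 in MCF7 and at 0.985 and 1.02 in T47D.

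MCF7 was fitted with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with 1 coefficient per group, TMM scaling, filterByExpr with a minimum count of 10, a robust quasi-likelihood F-test and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as changed. The comparisons were siHNRNPC against the mean of both controls, against siNC, against siLAMN, and siLAMN against siNC. The fit tested 13013 genes with 3 residual degrees of freedom and a biological coefficient of variation of 0.252. The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

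Whether replicate numbers pair the libraries was decided before any fits were compared. Deviations from the group means of same-numbered libraries correlated at 0.818, 0.835 and 0.831 over 9484 genes, so the pairing comes from the data and not from the labels. The fit without the number stayed the main one, and the number as a block was the alternative (coefficient of variation 0.0734, 2 residual degrees of freedom). Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 58.5, 41.7 and 48.2 for siHNRNPC, siLAMN and siNC.

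For T47D, log2 ratios of TMM-scaled CPM with a prior count of 2 were taken for 13436 genes with at least 50 reads in either library, with exact 95% counting intervals from the binomial split of reads. Where 1 side held no read, the ratio is given as a bound against 3 reads. Genes called in MCF7 were followed there by their sign and by their median against 10000 random lists of the same size matched on mean expression.

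In all, 25 gene lists were tested in MCF7 with camera at a preset correlation of 0.01, adjusted over the lists, and were described in T47D by random lists. They held interferon-stimulated genes, interferons and receptors, nucleic acid sensors, NF-kB targets, MHC class I, mitosis, DNA replication, oestrogen response, p53 targets, the integrated stress response, endoplasmic reticulum chaperones, hnRNPs, the spliceosome, histones, cholesterol, glycolysis and hypoxia, mitochondrial messengers, ribosomal proteins, nuclear-retained RNAs, snoRNA hosts, luminal, basal, fibroblast and leukocyte markers, and lamins with laminins.

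Genes were named by rule. HNRNPC came first, then the 8 largest rises and 8 largest falls against both controls among called genes with a mean of at least 1 CPM and the same sign against each control. The 3 changed members with the smallest adjusted p of each list with at least 3 changed members followed, or all of them where fewer changed. The siLAMN comparison named the 4 largest rises and falls and the lamin and laminin genes, and T47D its 8 largest rises and falls. IFNB1, IFNL1, IFNL2, IFNL3, DDX58, IFIH1, ADAR and EIF2AK2 were named whatever their values. After values were seen, 3 members were added from each list where at least 10 moved one way in the blocked fit, with the smallest blocked adjusted p in that direction, and blocked siLAMN genes by the same rule of 4.

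Alternatives were total count scaling, DESeq2 size factors in the edgeR fit, no filter on low counts, a DESeq2 1.42.0 Wald test, a non-robust fit, a test against a fold of 1.5, only the libraries of the groups compared, both cell lines with the line as a covariate, each library left out in turn, the replicate block, camera with an estimated correlation, and fry. For T47D they were total count scaling, prior counts of 0.5 and 5 and minima of 20 and 200 reads. After the data were seen, total count scaling, protein-coding genes only, offsets for GC content and length, a fold of 1.5, DESeq2 and left-out libraries were also run with the block. The MCF7 principal components used genes with a mean log2 CPM over 3, with a prior count of 2. The log2 ratios within replicates had 0.5 CPM added, which shrinks them at low counts. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

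The fits were tested on simulated data made from these libraries, for siHNRNPC against both controls. Of genes given folds of 1.5, 2 and 4, the fit without the block recovered 0%, 6% and 84.8% with 0 false calls of 60, and that with the block 82.1%, 97% and 100% with 3 false calls of 189. DESeq2 without the block recovered 1.5%, 46.3% and 100% with 0 false calls of 98. The counts were drawn with the blocked fit's own spread and replicate effect, so the better recovery with the block was built in. They cannot show how reliable the blocked calls are in the real data. The changed genes were well-covered ones, so recovery at low counts was not tested.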

Results

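Cytoplasmic RNA was profiled by sequencing in 2 human breast cancer cell lines, MCF7 and T47D, after transfection of an siRNA against HNRNPC or of a control siRNA. Both lines are oestrogen receptor-positive and of luminal type. HNRNPC is a nuclear protein that binds newly made transcripts and uridine-rich stretches in them. The series asks how HNRNPC bears on the interferon response to double-stranded RNA, and its design text names both the siNC and the siLAMN transfections as controls. The siRNAs were used at 10 nM, the medium was changed after 6 h and the cells were collected at 48 h. MCF7 had 2 libraries for each of siHNRNPC, siNC and siLAMN, and T47D had 1 library for siHNRNPC and 1 for siNC.

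The MCF7 siHNRNPC libraries held 7300809 and 7487537 reads assigned to genes. The siNC libraries held 6308165 and 9257355, and the siLAMN libraries 7125484 and 6043157. The T47D libraries were deeper, with 17511377 reads after siHNRNPC and 14764395 after siNC. The nuclear-retained RNA MALAT1 took 0.902% and 1.05% of their reads, against 0.0143% to 0.0387% in MCF7. For 7SK RNA the shares were 4.83% and 3.72%, against 0.739% to 1.90%. The T47D fractions may therefore hold more nuclear RNA, or the lines may differ in these RNAs, which was not tested. Values of the 2 lines may not be like for like. Values are given as TMM-scaled CPM with the SD over the libraries of a group. In MCF7, 3 reads stood for 0.324 to 0.496 CPM of total reads, before TMM scaling, depending on the library. Counting intervals and read floors given here cover counting error only. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries. The T47D pair had no replicate, so its values carry no SD and no p-value.

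HNRNPC was lower in every library that received its siRNA. The gene (ENSG00000092199.17) lies on chromosome 14, 21209136 to 21269494, minus strand, in the GRCh38 annotation of GENCODE 29, as do all positions below. In MCF7 it stood at 212 ± 29.4 CPM (SD, n = 2) after siHNRNPC, 688 ± 83.7 CPM (n = 2) after siNC and 631 ± 15.6 CPM (n = 2) after siLAMN. Against both controls this was 3.11-fold lower, a log2 fold change of -1.64 (SE 0.15, edgeR adjusted p = 0.00478). The log2 ratio was -1.57 within replicate 1 and -1.70 within replicate 2, and the call held without any 1 of the 6 libraries, with edgeR adjusted p from 0.0125 to 0.0447. T47D gave 1233 reads after siHNRNPC and 3976 after siNC, a log2 ratio of -1.89 (95% counting interval -1.99 to -1.80).

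**Figure D1:**
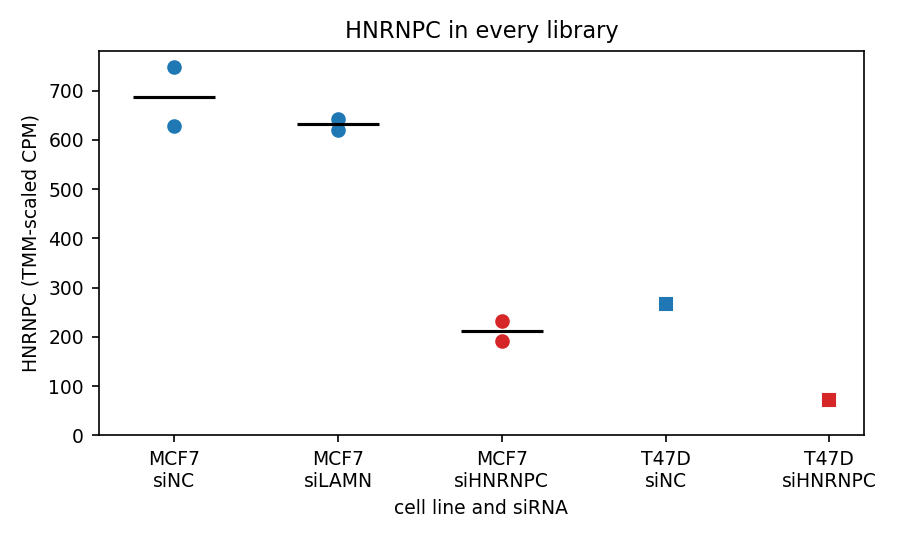
HNRNPC in TMM-scaled CPM (vertical axis, from 0) in each of the 8 libraries, grouped by cell line and siRNA; points are single libraries, red for siHNRNPC and blue for controls, and black lines are group means. The siHNRNPC libraries of each line sit below that line's control libraries, with means of 212 CPM against 688 and 631 CPM in MCF7.

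The MCF7 libraries differed by replicate number as well as by siRNA. The component that held 52.2% of the variance separated replicate 1 from replicate 2 in all 3 groups, and the next, with 33.7%, separated siHNRNPC from both controls. Mitochondrial ribosomal RNA took 1.36% to 1.56% of reads in the libraries numbered 1 and 0.000629% to 0.000708% in those numbered 2. Each comparison is therefore given as fitted without the replicate number, as fixed in the design, and, for most calls that it moved, also with the replicate number as a block.

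**Figure D2:**
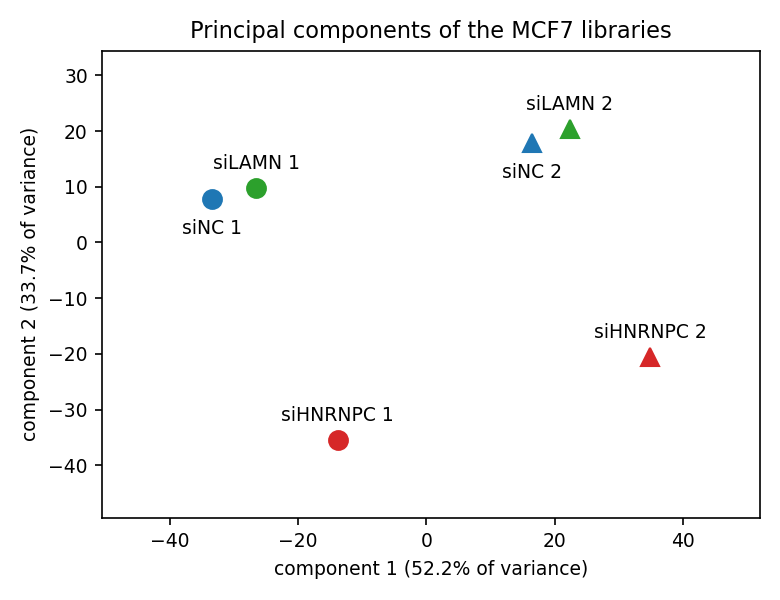
Principal components of the 6 MCF7 libraries from log2 CPM, component 1 on the horizontal axis and component 2 on the vertical axis, with circles for replicate 1 and triangles for replicate 2 and a colour per siRNA. Replicate numbers part along component 1 (52.2% of variance) and siHNRNPC parts from the controls along component 2 (33.7%).

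The main comparison asked which cytoplasmic transcripts differ in MCF7 after siHNRNPC from both sets of controls pooled. The response was led by antiviral and antigen presentation genes. IFI44L, XAF1, OAS2 and IFIT3, with means of 0.119 to 3.58 CPM in the controls, rose to means between 114 and 522 CPM, and messengers of interferon beta and of the lambda interferons were detected after siHNRNPC at 2.17 to 9.48 CPM. Without the replicate block fewer genes fell than rose, while with it the counts were close, and those that fell in both fits included HNRNPC itself, DOCK1, ACO1 and the ribosomal protein messengers RPS3A and RPLP0. Of 13013 genes tested, 134 rose and 22 fell (edgeR, adjusted p under 0.05), and every one of them had that sign within both replicates. Those ratios come from the same libraries as the calls, so the agreement in sign is no separate support. With the replicate block 1746 rose and 1760 fell, and 133 of the 134 and all 22 were among them. With total count scaling 110 rose and 41 fell. Leaving out siHNRNPC replicate 1 gave 73 up and 2 down, siHNRNPC replicate 2 gave 90 and 3, siNC replicate 1 gave 72 and 2, siNC replicate 2 gave 79 and 3, siLAMN replicate 1 gave 93 and 6, and siLAMN replicate 2 gave 92 and 8.

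Genes that interferons switch on rose together. Of the 56 members of the interferon-stimulated list tested, 53 rose and none fell, with a median log2 fold change of 4.20. Adjusted over the list alone all 56 rose, and with the replicate block all 56 rose over all genes. The median log2 ratio was 4.27 within replicate 1 and 3.34 within replicate 2. TRIM22, HELZ2 and PNPT1, named here after their values were seen, did not pass without the block, at log2 fold changes of 3.25, 2.46 and 1.26. IFI27 (chromosome 14, 94104836 to 94116698) stood at 525 ± 13.9 CPM (n = 2) against 5.11 ± 1.74 CPM (n = 4), a log2 fold change of 6.69 (SE 0.29, edgeR adjusted p = 0.000593). OAS1, which makes the 2'-5' oligoadenylates that activate RNase L, reached 251 ± 73.1 CPM against 3.45 ± 0.834 CPM (log2 6.17). IFITM1, a membrane protein that restricts virus entry, reached 422 ± 136 CPM against 11 ± 2.65 CPM (log2 5.30). IFITM genes are near-identical to each other, so the share of each is uncertain. Called also with an estimated correlation (camera adjusted p = 0.0477), the list lost its call when that was combined with the replicate block, where no list passed (lowest adjusted p = 0.232).

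The largest rises were all in genes known from the interferon response. IFI44L (chromosome 1, 78619922 to 78646145) stood at 114 ± 89.4 CPM (n = 2) against 0.119 ± 0.149 CPM (n = 4), with 1183 and 408 reads after siHNRNPC, 1 and 3 after siNC and 0 in both siLAMN libraries, so no fold change is given. Its neighbour IFI44 rose by 7.48 on the log2 scale. XAF1 (chromosome 17, 6755447 to 6775647), a pro-apoptotic protein, stood at 214 ± 95.1 against 0.461 ± 0.368 CPM (log2 8.79), and OAS2 at 522 ± 267 against 1.53 ± 1.09 CPM (log2 8.37). IFIT3, which binds foreign RNA in complex with related proteins, stood at 461 ± 172 against 3.58 ± 2.04 CPM (log2 7.0). SAMD9L had 347 reads in the 2 siHNRNPC libraries and 2 in the 4 control libraries, a ratio of 339 (95% counting interval 93.1 to 2810). RTP4 had 132 reads against 1 (ratio 258, 45.5 to 10261), and APOL1, a secreted lytic protein, 303 against 3 (ratio 197, 66.9 to 962). The edgeR adjusted p of these 8 genes lay between 0.00116 and 0.00914. The call of IFI44L was lost without siNC replicate 1 (edgeR adjusted p = 0.0640) or siNC replicate 2 (0.0695), and that of SAMD9L likewise (0.0640 and 0.0623).

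Messengers of interferons themselves appeared after siHNRNPC at low counts. IFNB1 (chromosome 9, 21077105 to 21077963), which encodes interferon beta, had 142 reads in the 2 siHNRNPC libraries and 3 in the 4 control libraries, a ratio of 92.5 (31.0 to 454; edgeR adjusted p = 0.00302). IFNL1 (chromosome 19, 39296325 to 39298673) stood at 5.90 ± 0.115 CPM against 0.168 ± 0.243 CPM (log2 5.09, edgeR adjusted p = 0.0329). Its reads were 40 and 47 after siHNRNPC, 0 and 5 after siNC and 0 and 1 after siLAMN. The size of its rise therefore rests on few control reads, at log2 4.20 against siNC and 5.98 against siLAMN. IFNL2 had 32 reads against 1 (ratio 62.5, 10.4 to 2545; edgeR adjusted p = 0.0479). IFNL3 had 34 reads against 0, at least 22.1-fold higher against a floor of 3 reads over the controls, and passed only with the block (edgeR adjusted p = 0.0619 without it, 6.5e-05 with it). IFNL2 and IFNL3 are near-identical copies whose reads cannot be assigned to either with certainty. Of the 9 interferon and receptor genes tested, 3 rose and none fell, 4 rose adjusted over the list alone and 7 rose with the replicate block. The median log2 fold change was 0.75, or 0.61 within replicate 1 and 0.81 within replicate 2 (camera adjusted p = 4.27e-11, and 0.0478 with an estimated correlation). IFNB1, IFNL1, IFNL2 and IFNL3 passed the read filter only through their siHNRNPC reads, which tilts this list's test upward. The IFNB1 call held without any 1 library. Those of IFNL1 and IFNL2 were lost without either siHNRNPC library (edgeR adjusted p = 0.135 and 0.155 for IFNL1, 0.236 and 0.286 for IFNL2) or either siLAMN library (0.0771 and 0.0611, 0.0965 and 0.0883), and that of IFNL2 also without siNC replicate 1 (0.171) or 2 (0.126).

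The sensors of foreign nucleic acid rose in part. Of 17 sensor and signalling genes tested, 7 rose and none fell, 9 rose and 1 fell adjusted over the list alone, and 11 rose and 1 fell with the block, the latter being MAVS, named after its value was seen. DDX58, the gene of the RNA sensor RIG-I (chromosome 9, 32455705 to 32526324), stood at 174 ± 45.5 CPM against 13.9 ± 3.53 CPM (log2 3.65, SE 0.25, edgeR adjusted p = 0.00148). IFIH1, the gene of the sensor MDA5 (chromosome 2, 162267079 to 162318703), stood at 233 ± 82.3 against 20.3 ± 3.43 CPM (log2 3.53, SE 0.23). IRF1, a transcription factor of the interferon response, rose by 2.63 on the log2 scale. EIF2AK2, the kinase PKR that double-stranded RNA activates (chromosome 2, 37099210 to 37157065), stood at 518 ± 171 against 122 ± 17.1 CPM (log2 2.1, SE 0.21). ADAR, which deaminates adenosine in double-stranded RNA (chromosome 1, 154582057 to 154628013), stood at 784 ± 128 against 331 ± 16 CPM (log2 1.24, SE 0.13, edgeR adjusted p = 0.00972). The ADAR call was lost without siHNRNPC replicate 1 (edgeR adjusted p = 0.0827) or siNC replicate 1 (0.0621). The list's median log2 fold change was 0.64, or 0.75 within replicate 1 and 0.47 within replicate 2. Its camera adjusted p was 1.1e-20, and 0.0629 with an estimated correlation.

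Of 17 tested members of the list of NF-kB target cytokines and regulators, 3 rose, 11 rose adjusted over the list alone and 16 rose with the block. None fell in any of these, and NF-kB activity itself was not measured. CCL5, a chemokine for T cells, stood at 32.9 ± 7.25 CPM against 1.76 ± 0.251 CPM (log2 4.21, SE 0.24, edgeR adjusted p = 0.00116). TNFSF10, the death ligand TRAIL, rose by 4.05 on the log2 scale (edgeR adjusted p = 0.0153). CXCL10, a chemokine that interferon induces, had 38 reads in the siHNRNPC libraries and 1 in the controls, a ratio of 74.2 (12.5 to 3008; edgeR adjusted p = 0.0446). NFKBIA, the inhibitor of NF-kB, had a log2 fold change of 1.06 without the block and 1.09 with it, and was called only with it (edgeR adjusted p = 0.244 and 3.2e-07). The median was 1.48 on the log2 scale, with 2.01 within replicate 1 and 1.14 within replicate 2 (camera adjusted p = 3.51e-17, and adjusted p = 0.0629 with an estimated correlation). The CXCL10 call was lost without each of the 6 libraries in turn (edgeR adjusted p from 0.0786 to 0.256). That of TNFSF10 was lost without siHNRNPC replicate 1 (0.0637), siNC replicate 1 (0.0832) or siNC replicate 2 (0.0695).

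MHC class I genes rose. Of 21 antigen presentation genes tested, 11 rose and none fell, 18 rose and none fell adjusted over the list alone, and 18 rose and 1 fell with the block, the latter being the chaperone CANX, named after its value was seen. B2M, the light chain of class I molecules (chromosome 15, 44711487 to 44718877), stood at 1317 ± 214 CPM against 230 ± 19.7 CPM (log2 2.52, SE 0.15, edgeR adjusted p = 0.00116). PSMB8, a subunit of the immunoproteasome, stood at 53 ± 9.26 against 1.16 ± 0.375 CPM (log2 5.50). HLA-B stood at 136 ± 31.9 against 4.44 ± 0.677 CPM (log2 4.94). HLA-A had a log2 fold change of 2.48 without the block and 2.50 with it, and was called only with it (edgeR adjusted p = 0.0867 and 1e-13). HLA genes vary between people and cell lines and resemble each other, so how reads divide between them is uncertain. The list's median log2 fold change was 2.48, or 2.57 within replicate 1 and 2.42 within replicate 2 (camera adjusted p = 1.19e-66, and 0.0477 with an estimated correlation).

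**Figure D3:**
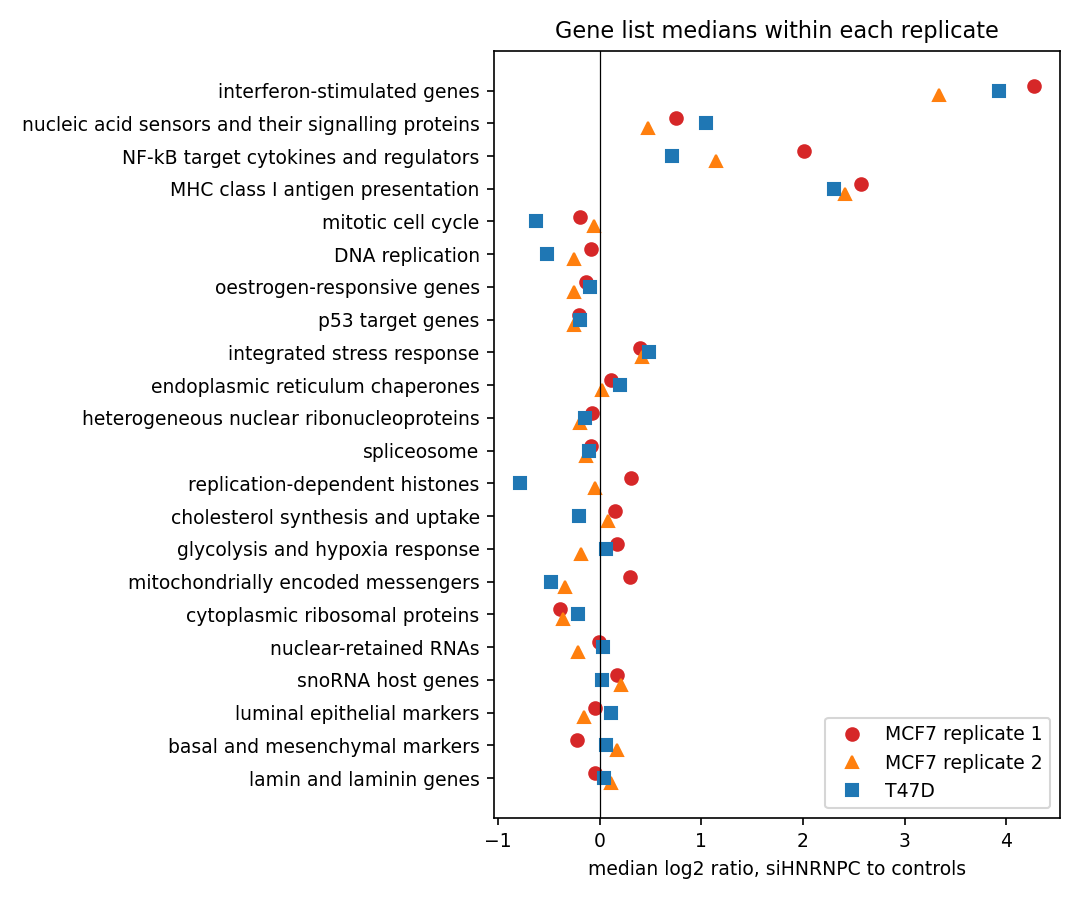
Median log2 ratio of siHNRNPC to controls (horizontal axis) of 22 of the 25 gene lists, within MCF7 replicate 1 (red circles), MCF7 replicate 2 (orange triangles) and in T47D against siNC (blue squares). The interferon-stimulated list lies at 4.27, 3.34 and 3.93, the MHC class I list at 2.57, 2.42 and 2.30, and the ribosomal protein list at -0.39, -0.36 and -0.21.

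Of 31 integrated stress response genes, SLC7A11 rose and none fell over all genes, 9 rose adjusted over the list alone, and 18 rose with the block while SHMT2 fell, named after its value was seen. SLC7A11, the cystine transporter (chromosome 4, 138164097 to 138242349), stood at 35.9 ± 0.185 CPM against 15.6 ± 0.702 CPM (log2 1.2, SE 0.15, edgeR adjusted p = 0.0186). With the block PPP1R15A, which reverses the phosphorylation of eIF2 alpha, rose by 1.45 on the log2 scale, and SLC3A2, an amino acid transporter chain, by 0.59. The list's median was 0.41, with 0.40 within replicate 1 and 0.41 within replicate 2 (camera adjusted p = 1.03e-07, and 0.0629 with an estimated correlation). The SLC7A11 call was lost without each of the 6 libraries in turn (edgeR adjusted p from 0.0667 to 0.181). None of 22 endoplasmic reticulum chaperones passed. With the block HSPA5, DNAJB11 and SEC24D rose while CANX, XBP1 and OSTC fell, named after their values were seen, and the list's camera adjusted p was 0.910. Its direction turned with the control, with a median of 0.23 and blocked counts of 9 up and 2 down against siNC, and -0.09 with 2 up and 5 down against siLAMN, while siLAMN lay at 0.22 against siNC with 7 up and 1 down.

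Ribosomal protein messengers were lower. Of 78 tested, RPS3A and RPLP0 fell and none rose, 29 fell adjusted over the list alone, and 64 fell with the replicate block. RPS3A (chromosome 4, 151099573 to 151104652) stood at 1021 ± 34.3 CPM against 1878 ± 212 CPM (log2 -0.87, SE 0.13, edgeR adjusted p = 0.0411). RPLP0 (chromosome 12, 120196686 to 120201235) stood at 1733 ± 161 against 3054 ± 188 CPM (log2 -0.82, SE 0.13, edgeR adjusted p = 0.0457). RPL7 had a log2 fold change of -0.83 in both fits and was called only with the block (edgeR adjusted p = 0.0781 without it, 8.5e-08 with it). The list's median log2 fold change was -0.37, with -0.39 within replicate 1 and -0.36 within replicate 2 (camera adjusted p = 3.36e-09, and adjusted p = 0.168 with an estimated correlation). Both single-gene calls were lost without each of the 6 libraries in turn (edgeR adjusted p from 0.0914 to 0.339), and processed pseudogenes of these genes make the assignment of reads uncertain.

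The largest falls other than HNRNPC were in genes of unlike function. DOCK1, an activator of the GTPase Rac (chromosome 10, 126905409 to 127452517), stood at 57.0 ± 3.42 CPM against 182 ± 21 CPM (log2 -1.67, SE 0.13, edgeR adjusted p = 0.00234), and its call held without any 1 library. ACO1, an aconitase that also binds iron-responsive elements (chromosome 9, 32384603 to 32454769), fell by 1.74 on the log2 scale. ZMAT3, a p53-induced RNA-binding protein, fell by 1.36, the zinc finger gene ZNF778 fell by 1.27 and the membrane protein gene CMTM4 fell by 1.18. The non-coding genes AC005332.5 and AC145207.5 fell by 1.98 and 1.88, but no strand setting was given and reads of overlapping genes cannot be told apart there. Leaving out 1 library ended the calls of ACO1 without siHNRNPC replicate 1 (edgeR adjusted p = 0.122) or either siNC library (0.0832 and 0.0579), of ZNF778 without either siHNRNPC library (0.143 and 0.120) or either siNC library (0.0696 and 0.0587), and of CMTM4 without either siHNRNPC library (0.146 and 0.124), siLAMN replicate 1 (0.0521) or siNC replicate 1 (0.0640). Those of ZMAT3 and AC145207.5 were lost without each of the 6 in turn (up to 0.224 and 0.284), and that of AC005332.5 without each except siLAMN replicate 1 (up to 0.277).

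Proliferation and hormone response lists gave no single call without the block except ZMAT3 of the p53 targets. None of the 37 mitotic genes or 43 DNA replication genes passed, over all genes or adjusted over the list alone. With the block 11 mitotic genes fell and CKS2 rose, and 15 replication genes fell while ORC6 and POLA2 rose, the risers being named after their values were seen. Blocked falls on the log2 scale were 0.64 for BUB1B, 0.51 for NUSAP1 and 0.37 for TOP2A, and for replication 0.89 for the ligase LIG1, 0.79 for UHRF1 and 0.56 for the helicase subunit MCM4. The list medians were -0.13 and -0.18 (camera adjusted p = 0.0414 and 0.00250, and adjusted p = 0.888 and 0.831 with an estimated correlation). The mitotic call was lost without siHNRNPC replicate 2 (camera adjusted p = 0.343), siNC replicate 1 (0.189) or siLAMN replicate 1 (0.327), and the replication call without siHNRNPC replicate 2 (0.478). Within replicates 1 and 2 the medians were -0.20 and -0.06 for the mitotic list and -0.08 and -0.25 for the replication list. The controls differed from each other here. The mitotic median was -0.23 against siNC and -0.03 against siLAMN, with 17 and 4 genes lower with the block, while siLAMN itself lay at -0.22 against siNC, with 7 lower. The replication median was -0.31 against siNC and -0.07 against siLAMN, with 17 and 10 lower with the block, and siLAMN lay at -0.20 against siNC, with 3 lower.

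Of 37 oestrogen-responsive genes none passed, 3 fell adjusted over the list alone, and 7 rose and 17 fell with the block, including CCND1 (cyclin D1), XBP1 and OLFM1, at blocked log2 values of -0.66, -0.56 and -0.75. That list's median was -0.21, with camera adjusted p = 0.0564 without the block, 0.0146 with it and 0.329 with the block and an estimated correlation. It passed without siHNRNPC replicate 1 (0.00458), siNC replicate 2 (0.0158) or siLAMN replicate 2 (0.00942).

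Of 33 p53 targets 1 fell, 3 fell adjusted over the list alone, and 15 fell with the block, including CMBL (-0.87) and FDXR (-0.82), while BBC3, GDF15 and XPC rose, named after their values were seen. The p53 list's median was -0.31 (camera adjusted p = 0.000757, and 0.0789 with an estimated correlation).

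RNA-processing lists shifted little. Of 32 heterogeneous nuclear ribonucleoproteins only HNRNPC itself fell, over all genes and adjusted over the list alone. With the block 10 fell, including PCBP2 (-0.48) and PTBP3 (-0.45), and HNRNPDL rose, named after its value was seen. The median was -0.13 (camera adjusted p = 0.0250, and 0.831 with an estimated correlation). That call was lost without siHNRNPC replicate 2 (0.741), siNC replicate 1 (0.173) or siLAMN replicate 1 (0.187). None of 52 spliceosome genes passed without the block. With it 12 fell, including DHX16 (-0.80), SNRPA1 (-0.74) and AQR (-0.72), and 5 rose, namely SF3B2, PHF5A, SNRPD1, SNRPG and SRSF4, named after their values were seen. The spliceosome median was -0.11 (camera adjusted p = 0.0564 without the block, 0.0396 with it and 0.658 with the block and an estimated correlation), and the list passed without siHNRNPC replicate 1 (0.00235), siNC replicate 2 (0.00910) or siLAMN replicate 2 (0.00942). None of 14 nuclear-retained RNAs passed (median -0.14, camera adjusted p = 0.574). With the block TUG1, RPPH1 and RMRP rose while MALAT1 and NORAD fell, named after their values were seen. Of 18 snoRNA host genes none passed (median 0.18, camera adjusted p = 0.309). With the block SNHG1, SNHG6, SNHG7, SNHG8 and EPB41L4A-AS1 rose and SNHG16 fell, likewise named after their values were seen.

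The remaining lists gave no call without the block except CD74 and LMNA. Of 38 replication-dependent histone genes 13 rose and 2 fell with the block, the latter being HIST1H1B and HIST1H4C, named after their values were seen. HIST2H2BE rose by 0.63, HIST1H2BJ by 0.86 and HIST1H2BB by 1.51 there, and near-identical copies make these uncertain. The histone median was 0.17, with 0.31 within replicate 1 and -0.04 within replicate 2 (camera adjusted p = 0.246 without the block, 0.0427 with it and 0.790 with the block and an estimated correlation). It passed upward without siHNRNPC replicate 2 (4.78e-08), siNC replicate 1 (0.0348) or siLAMN replicate 1 (0.00459) and downward without siHNRNPC replicate 1 (0.00783). The controls differed here too. Against siNC the histone median was 0.04, with 6 genes higher and 6 lower with the block, and against siLAMN it was 0.31, with 18 higher and none lower, while siLAMN lay at -0.26 against siNC, with 9 lower.

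Of 30 cholesterol genes 9 rose and 3 fell with the block (median 0.09, camera adjusted p = 0.318), the falls being DHCR24, FASN and ACACA, named after their values were seen. Of 27 glycolysis and hypoxia genes ADM and P4HA2 rose and GAPDH, ENO1, LDHA, EGLN3 and HIF1A fell with the block, named likewise. That list's median was -0.03, its mean 0.06 and its camera adjusted p 0.960. It too turned with the control, at 0.14 with 4 up and 1 down with the block against siNC and -0.07 with 0 up and 6 down against siLAMN, while siLAMN lay at 0.25 against siNC. Of 13 mitochondrially encoded messengers MT-ATP8 alone, named after its value was seen, rose with the block (median 0.14, within replicates 0.29 and -0.34, camera adjusted p = 0.981), and the list passed downward without siHNRNPC replicate 1 (0.00141) and upward without siHNRNPC replicate 2 (0.00246).

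Of 22 luminal markers 10 fell with the block, including KRT18 (-0.41), PGR (-0.62) and XBP1 (-0.56), and GATA3, CLDN4 and CLDN7 rose, named after their values were seen (median -0.15, camera adjusted p = 0.309). Of 11 basal and mesenchymal markers tested KRT17 rose and ITGA6 and LGALS1 fell with the block, named likewise. The median was 0.09, while camera's direction was down (adjusted p = 0.910). Against siNC the basal median was 0.24, with 3 up and 0 down with the block, and against siLAMN it was -0.36, with 1 up and 4 down, while siLAMN lay at 0.64 against siNC. Of 4 fibroblast markers COL5A1 fell with the block, also named after its value was seen, and the median of 0.06 again stood against a downward camera direction (adjusted p = 0.848), with 0.05 against siNC and -0.28 against siLAMN. Of 20 leukocyte markers CD74 and HLA-DRA passed the read filter. CD74, the invariant chain of class II molecules, had 53 reads after siHNRNPC against 1, a ratio of 104 (17.8 to 4166; edgeR adjusted p = 0.0278). Its call was lost in every leave-out except without siLAMN replicate 1 (up to 0.182). Adjusted over the list alone both rose, and HLA-DRA had 13 and 18 reads against 0 in the controls. The leukocyte median was 6.71, or 5.41 with HLA-DRA at its bound (camera adjusted p = 1.1e-08, and 0.0785 with an estimated correlation). Both genes passed the read filter only through their siHNRNPC reads, so the filter itself set the upward direction. The test therefore does not bear on leukocyte markers as a group. Both genes can also be induced by interferon in epithelial cells.

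Taken against each control alone, the same named genes kept their direction, in part by the rule that named them. The 2 comparisons share the siHNRNPC libraries with each other and all libraries with the comparison above, so they are not independent of it. Against siNC, 73 genes rose and 7 fell (edgeR, adjusted p under 0.05), and 1543 rose and 1593 fell with the block. With total count scaling 69 rose and 18 fell. Against siLAMN, 76 rose and 5 fell, and 1319 rose and 1438 fell with the block. By rule, 38 genes were called and named from the comparison with both controls, 28 higher and 10 lower. Genes named from T47D or from the blocked fits are not counted. All 38 had the same sign against siNC and against siLAMN, and 26 were called against each. For the largest rises and falls that agreement in sign was a condition of naming, so it is not a finding. With the block all 38 were called against each. HNRNPC fell by 1.70 on the log2 scale against siNC (edgeR adjusted p = 0.0104) and by 1.57 against siLAMN (0.0131), and ADAR rose by 1.29 and 1.2.

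The interferon-stimulated list had 40 of 56 members up and none down against siNC, and 41 up and none down against siLAMN, with medians of 4.05 and 4.17, and with the block 55 and 54 rose. MHC class I genes rose in 7 and 8 of 21 members, or 18 and 17 with the block, and the sensors in 6 and 5 of 17, or 11 and 10 with the block. With the block 64 of 78 ribosomal protein messengers fell against siNC, where none fell without it, and 52 fell against siLAMN. The count against siNC rested on its replicates. Without siNC replicate 1 no gene was called by edgeR, with 919 genes at an unadjusted p under 0.05, and without siNC replicate 2 the counts were 17 up and none down. The others were 53 and 2 without siHNRNPC replicate 1, 73 and 1 without siHNRNPC replicate 2, 80 and 4 without siLAMN replicate 1, and 78 and 4 without siLAMN replicate 2. Against siLAMN the counts were 57 and 0 without siHNRNPC replicate 1, 73 and 1 without siHNRNPC replicate 2, 27 and 1 without siLAMN replicate 1, 42 and 0 without siLAMN replicate 2, 63 and 3 without siNC replicate 1, and 65 and 3 without siNC replicate 2.

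The controls were also set against each other, to show how far they differ. LMNA, the gene of lamins A and C (chromosome 1, 156082573 to 156140089), was the gene that stood out. It had 118 and 134 reads in the siLAMN libraries, 680 and 1849 in the siNC libraries and 956 and 1956 in the siHNRNPC libraries, or 19.3 ± 2.71, 152 ± 55.2 and 193 ± 70.1 CPM (n = 2 each). No gene passed for siLAMN against siNC in edgeR, with 432 genes at an unadjusted p under 0.05, while DESeq2 called 7 higher and 4 lower. LMNA had a log2 fold change of -2.98 (SE 0.37, edgeR adjusted p = 0.856). With the replicate block 375 genes were higher and 281 lower in siLAMN, and LMNA was lower by a log2 fold change of -2.95 (edgeR adjusted p = 1.1e-10). Among the other lamin and laminin genes, LAMC2 rose by 1.73 and LAMC1 by 0.75 with the block, and no other member passed. The largest blocked changes, a selection made after values were seen, were falls of 2.29 for LINC00689, 1.59 for the scramblase XKR8 and 1.53 for the protease inhibitor CSTA. The keratins KRT17 and KRT16 rose by 2.49 and 2.76 and OLFML3 rose by 3.19. AC008695.1 had 37 and 21 reads in the siLAMN libraries and 0 in the siNC libraries, in a locus where overlapping genes cannot be told apart.

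Lamin and laminin genes as a list did not pass after siHNRNPC, with 1 of 12 members called up, a median log2 fold change of 0.04 and camera adjusted p = 0.692, though it passed without siHNRNPC replicate 1 (0.0276). The list's median was 0.20 against siNC and -0.15 against siLAMN. The member called was LMNA, at 1.83 on the log2 scale against both controls (SE 0.28, edgeR adjusted p = 0.0445). The siLAMN libraries are among those controls: LMNA rose by 3.32 against siLAMN (edgeR adjusted p = 0.0174), while against siNC its log2 value was 0.34 (edgeR adjusted p = 0.754 without the block, 0.0144 with it). The call against both controls was lost without siHNRNPC replicate 2 (0.246), either siLAMN library (0.125 and 0.0911) or either siNC library (0.114 and 0.0575). With the block LAMA3 and LAMB1 rose and LMNB1 and LMNB2 fell against both controls, named after their values were seen. Of the 56 interferon-stimulated genes none was called between the controls without the block, and the median was -0.14. With the block BST2 rose and DTX3L fell in siLAMN against siNC, named after their values were seen.

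T47D was compared as 1 library against 1, to see the same knockdown in another line. Interferon-stimulated genes again led. IFIT2 went from 9 reads after siNC to 3642 after siHNRNPC, a log2 ratio of 8.19 (95% counting interval 7.53 to 9.59). IFI27 went from 38 to 11940 reads (8.02), IFIT1 from 54 to 15549 (7.92), XAF1 from 9 to 2864 (7.84), OASL from 36 to 8400 (7.59) and IFIT3 from 39 to 8219 (7.45). RSAD2, an enzyme that makes a chain-terminating nucleotide, had 611 reads against 0, at least 177-fold higher against a floor of 3 reads, and IFI44 had 702 against 1, a ratio of 610 (109 to 24116). Of 13436 genes with at least 50 reads in either library, 449 were at least 2-fold higher and 142 at least 2-fold lower.

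Interferon messengers were detected in T47D after siHNRNPC and not after siNC. IFNB1 had 22 reads against 0, at least 6.37-fold higher, IFNL1 129 against 0, at least 37.3-fold, IFNL2 37 against 0, at least 10.7-fold, and IFNL3 52 against 0, at least 15.1-fold. CXCL10 had 42 against 0, at least 12.2-fold higher. The sensors DDX58 and IFIH1 had log2 ratios of 4.47 (4.24 to 4.74) and 3.91 (3.66 to 4.23), EIF2AK2 1.74 (1.62 to 1.86) and ADAR 1.55 (1.51 to 1.60). HLA-A went from 957 to 19921 reads (4.17), HLA-B from 4713 to 41511 (2.94) and B2M from 2840 to 24060 (2.88). IFI44L had 752 reads against 2, a ratio of 327 (90.1 to 2702), and SLC7A11 a log2 ratio of 1.12 (0.66 to 1.67).

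Falls in T47D included the target and genes of unlike kinds. CBX5, which encodes heterochromatin protein 1 alpha (chromosome 12, 54230940 to 54280133), went from 7737 to 2003 reads, a log2 ratio of -2.15 (-2.22 to -2.08). In MCF7 its log2 fold change was -1.29 (edgeR adjusted p = 0.0715 without the block, 3.7e-08 with it). The keratin KRT13, oestrogen-responsive, went from 445 to 84 reads (-2.58), and in MCF7 its log2 fold change was -1.54 (edgeR adjusted p = 0.199, and 0.000918 with the block). CCDC88A, an actin-binding protein, had a log2 ratio of -2.05 (-2.85 to -1.48) from 92 and 24 reads. Of the largest falls in MCF7, DOCK1, ZNF778, CMTM4 and AC145207.5 had T47D log2 ratios of -1.71, -1.22, -1.63 and -1.69. ACO1, ZMAT3 and AC005332.5 fell less than in MCF7, at -0.52, -0.66 and -0.43. The other genes of the largest falls in T47D are ones whose reads are hard to assign. EIF3CL, a near-identical copy of EIF3C, went from 828 to 59 reads (-3.97). TBC1D3F, of a family of near-identical copies, had 0 against 58 reads, at least 22.3-fold lower, and AC008695.1 had 0 against 55, at least 21.1-fold lower. AL354740.1 (-2.43) and AC004656.1 (-2.23) lie in loci where strand was needed.

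Gene lists in T47D were described by where their median lay among 10000 random lists matched on expression. The interferon-stimulated median of 3.93 lay above all of these, whose central 95% spanned -0.10 to 0.10, and all 57 members were positive. MHC class I (2.30), nucleic acid sensors (1.05), NF-kB targets (0.71) and the integrated stress response (0.48) also lay above all random lists, while interferons and receptors (0.30) lay at percentile 91.0. All 37 mitotic genes were negative, with a median of -0.62, and 42 of 43 DNA replication genes, with a median of -0.52, and both medians lay below all random lists. Histone genes lay at -0.78, with 36 of 37 negative, below all random lists, mitochondrially encoded messengers at -0.48 (percentile 0.03), and ribosomal proteins at -0.21 with 66 of 78 negative (percentile 0.01). Cholesterol genes lay at -0.21 (percentile 0.450) and p53 targets at -0.19 (percentile 0.550). Endoplasmic reticulum chaperones lay at 0.20 (percentile 99.8), luminal markers at 0.11 (percentile 98.8) and 4 leukocyte markers at 2.94, above all random lists. The oestrogen (-0.10), hnRNP (-0.14), spliceosome (-0.10), glycolysis (0.06), nuclear-retained (0.03), snoRNA host (0.03), basal (0.07), fibroblast (0.23) and lamin (0.04) lists lay within the central 95% of their random lists. Members of a list move together, unlike random genes, and T47D had no replicate, so these positions are not p-values. Any difference between the T47D libraries could move a list. Between the MCF7 controls, siLAMN against siNC, the medians were -0.22 for mitosis, -0.20 for DNA replication, -0.26 for histones, -0.04 for mitochondrial messengers and -0.13 for ribosomal proteins.

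Genes called in MCF7 were followed in T47D, which shares no library with them. Of 128 genes called up against both controls and with enough reads in T47D, 126 were higher there (98.4%, exact binomial interval 94.5% to 99.8%), against 50.3% of all genes, with a median log2 ratio of 3.0. The exceptions, named after their values were seen, were STON2 (-0.36) and AC091057.1 (-0.31). Of 22 called down, 21 were lower in T47D (95.5%, 77.2% to 99.9%), with a median of -0.77, the exception being PREX1 (0.22), likewise named. Both medians lay outside all 10000 matched random lists, and genes of 1 pathway move together, so the intervals treat as independent what is not. Of these, 114 and 6 changed at least 2-fold in the same direction. Genes called in MCF7 with the replicate block had the same sign in 79.7% of 1599 up and 83.9% of 1668 down, with medians of 0.30 and -0.28.

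**Figure D4:**
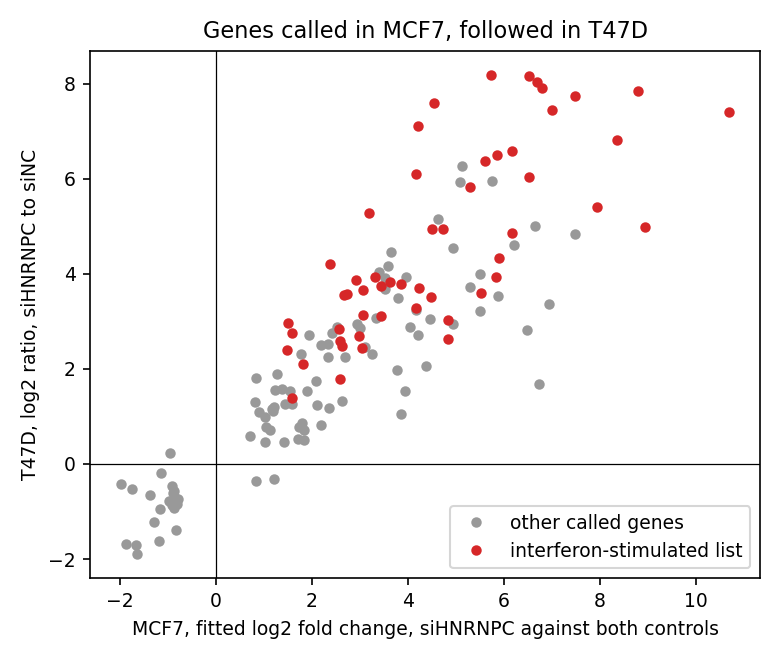
Genes called in MCF7 against both controls, with the fitted log2 fold change in MCF7 on the horizontal axis and the log2 ratio of siHNRNPC to siNC in T47D on the vertical axis; red points are members of the interferon-stimulated list and grey points other called genes. Of the genes called up 126 of 128 lie above 0 in T47D, and of those called down 21 of 22 lie below 0.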

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

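Of the tests below, those of the ribosomal protein composition and of the replicate split were fixed before their results were seen, and the others were chosen after. Some results lay on opposite sides of 0 in MCF7, in both replicates, and in T47D, and none of these differences was tested. The histone gene HIST1H2BJ had log2 ratios of 1.02 and 0.68 within the MCF7 replicates and -0.8509 in T47D. The histone gene HIST1H2BB had 1.62 and 1.22 within the MCF7 replicates and -0.3373 in T47D. The keratin KRT18 had -0.34 and -0.47 within the MCF7 replicates and 0.1776 in T47D. The laminin chain gene LAMA3 had 0.29 and 0.59 within the MCF7 replicates and -0.4839 in T47D. OLFML3 had -1.48 and -2.44 within the MCF7 replicates and 0.4735 in T47D, but T47D had siNC alone, and in MCF7 OLFML3 stood at 0.993 CPM after siHNRNPC, 1.93 after siNC and 18.1 after siLAMN, with a blocked log2 of -0.91 against siNC (edgeR adjusted p = 0.261). The median of the cholesterol list was 0.15 and 0.08 within the MCF7 replicates and -0.207 in T47D.

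The rise of interferon-stimulated genes in MCF7 was set against 3 other explanations. The values argue against leukocytes among the cells as its source, by a bound set after they were seen. The 18 markers other than CD74 and HLA-DRA summed to 2.67 ± 0.602 CPM after siHNRNPC and 1.56 ± 0.305 CPM in the controls. That is a difference of 1.113 CPM, and PTPRC had 0 reads. A response to any targeted siRNA was excluded, since the list's median was -0.1399 for siLAMN against siNC. The series held 1 siRNA label against HNRNPC, so an effect of that oligonucleotide other than through HNRNPC cannot be told apart from loss of the protein. The rise in both lines could follow from loss of HNRNPC, and a second siRNA or a rescue would be needed to tell.

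The fall of ribosomal protein messengers was set against GC content and length, against composition and against a shared 5' terminal oligopyrimidine tract. With offsets for GC content and length in the blocked fit the list's median was -0.4807, which argues against that bias, by a bound set after values were seen. GC content and length were those of each gene's longest annotated transcript, which need not be the expressed one. The bias was therefore not excluded. Without the interferon lists and non-coding genes it was -0.3627, so the fall did not need those genes in the counts. Both fits used TMM scaling, which already allows for composition, and other genes that rose stayed in. This value therefore cannot exclude composition as the cause. Of 18 other messengers with such a tract 15 fell in the blocked fit, and in T47D 16 of 18 had intervals below 0 with a median of -0.55. Ribosomal protein messengers had a smaller T47D median of -0.21, with 66 of 78 negative. The fall may be one of messengers with this tract, but the sets did not fall alike in T47D. No other abundant messengers were set beside them, and whether their level, location or translation changed was not tested.

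The split of the MCF7 libraries by replicate number was set against ribosomal RNA carry-over and GC content with length. With protein-coding genes only the lowest correlation of same-numbered deviations was 0.7283, so the split did not need ribosomal RNA reads in the counts. TMM scaling already allows for such reads, so a low correlation was unlikely from the start. An effect on other genes of the step that removed ribosomal RNA was not excluded. GC content and length took 43.43% of the variance of the replicate difference over 9658 genes. The median log2 difference was -0.23 in genes with up to 41.4% GC and 0.45 in genes with at least 55.5%. Mitochondrial ribosomal RNA took 1.36% to 1.56% of reads in replicate 1 and 0.000629% to 0.000708% in replicate 2. Mitochondrial messengers took 0.774% to 0.918% and 0.376% to 0.489%. For mitochondrial ribosomal RNA this argues against a difference between cultures alone. For the other genes a difference in library preparation cannot be told apart from one between cultures. No biological explanation was tested.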

How the results depend on the processing

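The 38 genes called and named by rule from the comparison with both controls, not counting those named from T47D or the blocked fits, kept their call and sign in the replicate block, and the cause was not tested for any change given here unless stated. Among named genes against both controls, the block also gave calls for AC004656.1 (log2 -1.18, edgeR adjusted p = 7.2e-06), XKR8 (1.60, 0.000149), CSTA (1.2, 0.00366) and OLFML3 (-2.51, 0.000758), the last 2 not called with the block against siNC alone (CSTA 0.43, 0.318; OLFML3 -0.91, 0.261), and beyond these and those given in the report it changed no other call there. Against siNC or siLAMN alone it gave further calls that are not listed. Depth of 6043157 to 9257355 reads limits what MCF7 can show. Before TMM scaling 3 reads equal up to 0.496 CPM, and IFNB1, IFNL2 and IFNL3 lie below 3 reads in every control library. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the other groups. Of named gene values under alternatives, 7266 stayed the same, 1839 gained and 324 lost their call in the same direction, 7 moved and 1 reversed. MCF7 values called in neither setting counted as the same whatever their sign, also for siLAMN against siNC. The value reversed is therefore not a count of all sign changes, and the list tests were counted likewise. Of the list tests, 291 stayed the same, 20 gained and 37 lost their call and 2 reversed. Of counts and shares, 83 stayed the same and 157 moved. Of the 38 genes, 20 kept their call in every leave-out, 35 in the non-robust fit, 30 with total count scaling and 27 with a fold of 1.5. With the block and a library left out, DDX58, IFIT3 and OAS2 lost theirs without siLAMN replicate 1 (edgeR adjusted p = 0.0805, 0.126 and 0.111) or 2 (0.126, 0.144 and 0.125).

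Against both controls, where 134 genes rose and 22 fell, the counts up and down were 221 and 163 with DESeq2, 491 and 309 with no filter, 93 and 3 with a fold of 1.5, and 110 and 41 with total count scaling. With the replicate block they were 1746 and 1760, with the block and DESeq2 546 and 767, with GC and length offsets 1436 and 2150, with protein-coding genes only 1670 and 1673, with a fold of 1.5 246 and 110, and with total count scaling 1676 and 1745. With each library left out, with and without the block, counts ranged from 72 to 1600 up and from 2 to 1714 down.

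Against siNC, where 73 rose and 7 fell, they were 189 and 109 with DESeq2, 428 and 228 with no filter, 184 and 89 with both cell lines, 79 and 3 with only the groups compared, 62 and 2 with a fold of 1.5, and 69 and 18 with total count scaling. The replicate block gave 1543 and 1593, with the block and DESeq2 509 and 684, with GC and length offsets 1237 and 2012, with protein-coding genes only 1495 and 1529, with a fold of 1.5 267 and 104, and with total count scaling 1500 and 1569. With each library left out they ranged from 0 to 1524 up and from 0 to 1749 down.

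Against siLAMN, where 76 rose and 5 fell, they were 167 and 91 with DESeq2, 316 and 229 with no filter, 58 and 2 with only the groups compared, 66 and 3 with a fold of 1.5, and 66 and 9 with total count scaling. Under the replicate block they were 1319 and 1438, with the block and DESeq2 406 and 546, with GC and length offsets 1141 and 1766, with protein-coding genes only 1282 and 1379, with a fold of 1.5 193 and 95, and with total count scaling 1242 and 1391. With each library left out they ranged from 27 to 1420 up and from 0 to 1785 down.

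For siLAMN against siNC, where no gene passed in edgeR, they were 7 and 4 with DESeq2 and 44 and 14 with no filter. Blocking on replicate (the replicate block) gave 375 and 281, with the block and DESeq2 97 and 78, with GC and length offsets 306 and 278, with protein-coding genes only 397 and 293, with a fold of 1.5 17 and 6, and with total count scaling 370 and 244. With each library left out they ranged from 0 to 681 up and from 0 to 591 down.

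List calls in camera depended most on the correlation between genes. With an estimated correlation the adjusted p was 0.0629 for the sensors, NF-kB targets and integrated stress response, 0.888 for mitosis, 0.831 for DNA replication and hnRNPs, 0.0789 for p53 targets, 0.168 for ribosomal proteins and 0.0785 for leukocyte markers. With the replicate block and an estimated correlation it was 0.232 for interferon-stimulated genes, interferons, sensors, NF-kB targets, MHC class I, the integrated stress response and ribosomal proteins, 0.755 for mitosis, 0.658 for DNA replication, 0.329 for p53 targets and leukocyte markers, and 0.400 for hnRNPs. The rotation test fry asks another question, whether a list changed at all rather than more than other genes, and its adjusted p was 0.628, 0.520, 0.0521, 0.625 and 0.0515 for mitosis, DNA replication, p53 targets, hnRNPs and ribosomal proteins. With fry and the replicate block that was 0.234 for mitosis, 0.145 for DNA replication and 0.0633 for p53 targets and hnRNPs.

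With the replicate block, with it and total count scaling, and with it and GC and length offsets, camera's adjusted p was 0.0146, 0.0165 and 0.00566 for oestrogen-responsive genes and 0.0396, 0.0445 and 0.00667 for the spliceosome. For histones it was 0.0427 and 0.0445 in the first 2 of these, and for luminal markers 0.0244 in the last. With each library left out it ranged from 0.000342 to 0.343 for mitosis, 1.12e-06 to 0.478 for DNA replication, 0.00458 to 0.571 for oestrogen-responsive genes, 9.21e-05 to 0.741 for hnRNPs, 0.00235 to 0.694 for the spliceosome, 4.78e-08 to 0.917 for histones, 0.00141 to 0.530 for mitochondrial messengers and 0.0276 to 0.981 for lamins and laminins. Without siHNRNPC replicate 1 the direction reversed for histones (0.00783) and mitochondrial messengers (0.00141). The log2 fold change of EIF3CL in the blocked leave-outs ranged from -1.78 to 2.24, and without siNC replicate 2 it reversed at 2.24.

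In T47D, with minima of 20 and 200 reads, 743 and 243 genes were at least 2-fold higher and 259 and 74 at least 2-fold lower, as more or fewer genes entered. Genes called against siNC alone had the same sign in T47D in 100% of cases in each direction, with a median of 3.75 for those called up. Genes called with the replicate block had the same sign in 79.7% of those called up, with medians of 0.30 up and -0.28 down.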

Other observations

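All genes in this part and the next were chosen after values were seen, as were the tests on them. The genes below were picked because they passed against both controls in MCF7, so they say nothing of any group as a whole. APOL6, a neighbour of APOL1, rose by 6.94 on the log2 scale (edgeR adjusted p = 0.00125) and had a log2 ratio of 3.36 in T47D. BTN3A1, a butyrophilin seen by gamma delta T cells, rose by 4.38 (T47D 2.06), and the secreted glycoprotein gene LGALS3BP rose by 3.40 (T47D 4.04). SAMHD1, which degrades deoxynucleotides, rose by 2.70 (T47D 2.25), and PML, the core protein of nuclear bodies, rose by 2.43 (T47D 2.75). TRIM56 rose by 1.45 (T47D 1.27), the ubiquitin ligase RNF213 by 1.21 (T47D 1.19) and CASP8, the initiator caspase of death receptors, by 0.91 (T47D 1.09). ZC3HAV1, which binds CpG-rich viral RNA, rose by 0.82 (T47D 1.30).

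Of 18 messengers with a 5' terminal oligopyrimidine tract other than those of ribosomal proteins, EEF1A1, EEF1B2 and EEF1G passed without the block. EEF1A1 fell by 0.79 on the log2 scale (edgeR adjusted p = 0.0270), EEF1B2 by 0.80 and EEF1G by 0.92, with T47D log2 ratios of -0.73, -0.85 and -0.86. EIF2S3, the gamma chain of eIF2, fell by 0.92 (T47D -0.47). SEC23A, of the coat of vesicles leaving the endoplasmic reticulum, and ATL3, which joins its tubules, fell by 0.84 and 0.83 (T47D -0.77 and -1.38). Within the stress response, ATF4, ATF3, DDIT3 and CHAC1 were called only with the replicate block, at log2 fold changes of 0.51, 2.08, 1.38 and 1.70 without it and 0.52, 2.08, 1.39 and 1.71 with it, with T47D log2 ratios of 0.79, 0.34, 1.09 and 1.62.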
